A study of Homo sapiens with 10 samples.

How the data were processed

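Chromatin immunoprecipitation with sequencing (ChIP-seq) measured where a protein sat on the DNA of 22RV1 cells, an established human prostate cancer line. The labels name 10 samples, 1 per group: 6 immunoprecipitated libraries and 4 IgG libraries, the mock immunoprecipitations of the siRNA pair and of the 245-255 pair. The labels do not name the antibody. The series title is about TRIM24, a chromatin reader and transcription co-regulator. A peak list was analysed for each of the 6 immunoprecipitated libraries, and the IgG libraries were not analysed here. The groups were a control siRNA, an siRNA against RB1, an empty vector for the 245-255 experiment, a plasmid carrying HA-tagged RB residues 245-255, an empty vector for the RBN experiment, and a plasmid carrying the HA-tagged insert that the labels call RBN. One label field calls the HA-RB(245-255) library a control group while its title names the construct. The title was followed.

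Per the submitters' processing notes, bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2 and MACS2 2.1.0 were used with human genome build hg38, with no role or order given for them. Peaks were listed per library and not on pooled samples. The deposited lists have no header, and their values fit the narrowPeak layout with its name column left out. The fold enrichment of each peak is the authors' ratio of the signal at the summit to the caller's local background. The deposited lists also give the authors' −log10 p-value and −log10 q-value of each peak, and the distance of the summit from the peak start. These peak values are the authors' own and were used to describe, rank and filter peaks within a list. The smallest −log10 p-value in each list lay between 1.30 and 1.31, so the lists hold weak peaks as well as strong ones. Settings, control libraries and read numbers are not given in the sources used here.

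Overlaps, locations and counts were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Peaks on chromosomes 1-22, X and Y were used. A control peak was kept when it overlapped a condition peak by at least 1 bp, and a condition peak was new when it overlapped no control peak. The expected share came from 100 random placements of the control peaks on their own chromosomes. Chromosome lengths were taken as the largest coordinate listed. Shares carry exact Clopper-Pearson 95% intervals. With 1 library per group there are no replicates, no p-value can be given for any difference between conditions, and every interval covers counting error only.

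Gene positions came from a RefSeq table of GRCh38.p14 that holds 20037 protein-coding genes on these chromosomes, without strand, exons or sequence. Promoters were therefore replaced by gene ends, within 1 kb of either end of a gene. A transcription start cannot be told from a transcription end in this way. Summits were sorted into gene end, gene body and intergenic. Motif searches and matching of genes on CpG content need a genome sequence and were not run. A gene counted as listed only in the condition when a condition summit lay within 1 kb of either end and no control interval came within 1 kb of either end. The converse held for the control. Counts of gene ends in 1 library only are thus counts of genes, each counted once.

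Comparisons, alternatives, the rule for naming genes and 14 gene lists were fixed before the data were examined. Of 457 list symbols, 455 matched a gene. DUSP13 and DDX58 did not. The rule names RB1, TRIM24, DUSP2 and MTOR always. It adds, per comparison, the 10 gene ends with the highest fold enrichment among those listed only in the condition and the 10 among those listed only in the control. LOC, LINC and histone cluster symbols were left out, and genes sharing 1 peak count once. It also takes up to 4 members of each gene list, first those in 1 library only and then those in both, of which a selection is printed. Some genes that the rule takes are not reported here. A list's share of members with a summit at a gene end was placed as a percentile among 10000 random lists of the same size. A value from 2.5 to 97.5 was read as ordinary. These percentiles describe the libraries and are not tests between conditions. Across 14 lists and several libraries, some extremes arise by chance.

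The lists of the libraries with an IgG partner tiled nearly all of the chromosomes, so overlap alone could not separate them. Another measure was therefore chosen after the data were seen. In MACS2 the fold enrichment is the pileup plus 1 over the local background plus 1, and the p-value is a Poisson tail at that pileup and background. Both together give the number of DNA fragments stacked at each summit, so the authors' values enter this step across lists only as fragment numbers. In the lists with an IgG partner these numbers came in steps of 0.0166, 0.0176, 0.0434 and 0.0512, which were taken as the size of 1 scaled fragment. Where several solutions fitted, the lowest background within 0.01 of a whole fragment was taken. Such a choice arose for 5.55% of the control siRNA summits, 5.79% for RB1 siRNA, 6.00% for EV(245-255) and 15.1% for HA-RB(245-255). The recovery of fragment numbers was tested on a simulated list for each library. Only the presence of an IgG partner was taken from the library, and step, background and fragment numbers were drawn at random. The shares below therefore test the method and do not measure its error in the real lists. It returned the exact number for 99.98% of 14994 simulated summits for the control siRNA library and 100% of 19011 for RB1 siRNA. The shares were 99.995% of 19977 for EV(245-255), 99.9947% of 18947 for HA-RB(245-255), 99.9943% of 17568 for EV(RBN) and 99.9891% of 18419 for HA-RBN. The overlap count was tested on 5000 simulated peaks per comparison. It found the true shares of 36.96% for the siRNA pair, 37.38% for the 245-255 pair and 36.86% for the RBN pair.

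Enrichment is the fragment number at a summit over the most common background of its library. Summits of the libraries compared within 250 bp of each other were called shared, and those with at least 20 fragments summed over both libraries were used. The log2 ratio is the condition's enrichment over that of its control, with a 95% interval from the 2 fragment numbers. Ratios at gene ends were then set relative to the median of all shared gene ends of the comparison, which was −0.12 for RB1 siRNA, −0.47 for HA-RB(245-255) and 0.68 for HA-RBN. Relative medians of gene lists with at least 4 shared members were placed among random lists drawn from the shared gene ends. These random lists were matched by decile on the summed log2 enrichment of both libraries. The same computation between the control libraries, which received neither an RB construct nor RB1 siRNA, gives the spread between experiments, differences in peak listing included.

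The background per base, an index of depth, was 0.413 fragments in the control siRNA library, 0.539 in RB1 siRNA, 0.187 in EV(245-255), 0.250 in HA-RB(245-255), 0.367 in EV(RBN) and 0.634 in HA-RBN. The median summit held 6, 5, 3, 3, 3 and 3 fragments in the same order. A gene with 10 fragments or fewer in either library therefore has a wide interval.

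The alternatives were a reciprocal overlap of 50%, summits within 250 bp, both lists held to −log10 q of at least 5 or fold enrichment of at least 5, both lists at the same length, the scored list alone at −log10 q of at least 5, all sequences, and gene end windows of 500 bp and 2 kb. Alternatives added after the data were seen were absence of a summit in place of absence of an interval, minimums of 10 and 40 fragments, a summit distance of 100 bp, and a 2 kb window for the relative medians of the E2F and mitosis lists.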

Results

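ChIP-seq peak lists were analysed for 6 libraries of 22RV1 prostate cancer cells, with 1 library in each group and no replicates. The series title links the RB residues S249 and T252, the co-regulator TRIM24, mTOR signalling and the phosphatase DUSP2. RB, the product of RB1, is the tumour suppressor that restrains E2F transcription factors. Per library, 21666 peaks were listed for the control siRNA and 35285 for RB1 siRNA. The 245-255 pair had 77488 for its empty vector, EV(245-255), and 95816 for HA-RB(245-255). The RBN pair had 161012 for EV(RBN) and 252425 for HA-RBN. Read totals are not given in the sources used here. The background, an index of depth, ran from 0.187 fragments per base in EV(245-255) to 0.634 in HA-RBN. Peaks with −log10 q of at least 5 numbered 131, 83, 184, 230, 3204 and 10880 in that order. These numbers cannot be compared as strong sites between lists with and without an IgG partner. A fold enrichment of 5 needed 244, 231, 94 and 80 fragments in the lists with an IgG partner, and 6 and 8 in the RBN pair. Summits with at least 20 fragments numbered 4460, 5901, 4138, 4079, 1249 and 6017 in the same order.

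Gene ends carried more summits than chance in every library. Within 1 kb of an end of a protein-coding gene lay 23.3% of control siRNA summits (95% interval 22.7 to 23.8), 17.4% of RB1 siRNA summits (17.0 to 17.8), 11.3% in EV(245-255) (11.1 to 11.6), 9.15% in HA-RB(245-255) (8.97 to 9.34), 8.34% in EV(RBN) (8.20 to 8.47) and 6.78% in HA-RBN (6.68 to 6.88). Random points gave 2.36%. Among summits with at least 20 fragments the share was 62.8%, 61.2%, 53.1%, 51.8%, 34.9% and 50.04% in the same order. Gene bodies held 29.9%, 31.9%, 40.8%, 39.6%, 44.6% and 44.5% of all summits, and the rest were intergenic.

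DNA replication and E2F target genes stood out in each library, though other lists did in most. Of all genes, 28.1%, 33.5%, 45.4%, 45.5%, 60.2% and 73.4% had a gene end summit in the library order above. RB pathway genes lay at percentiles 99.98, 99.8, 98.3, 99.4, 95.85 and 99.9, and mitosis genes at 98.1, 98.8, 92.6, 99.6, 99.8 and 99.99. Each interval lists 1 summit, so with wide intervals these counts cannot be compared between libraries as binding. Of their 50 members, 31 had a summit at a gene end in the control siRNA library, 29 with RB1 siRNA, 37 in EV(245-255), 39 in HA-RB(245-255), 43 in EV(RBN) and 47 in HA-RBN. The lowest percentile of these shares among random lists was 99.96. mTOR signalling genes had such a summit in 20, 25, 33, 42, 43 and 50 of 55 members in that order, at percentiles 91.0, 96.4, 98.3, 100, 99.7 and 99.9. Members of the DUSP family, phosphatases that act on MAP kinases, had one in 8, 12, 16, 13, 19 and 20 of 22. Their percentiles were 80.1, 97.7, 99.5, 89.3, 99.5 and 97.4, ordinary with the control siRNA, in HA-RB(245-255) and in HA-RBN. For cytosolic ribosomal proteins the numbers were 22, 25, 37, 37, 58 and 61 of 62. Genes specific to other organs were the reverse, with 1, 5, 9, 6, 16 and 18 of 43, and no percentile above 0.185. CEL and PRSS1 of the pancreas were among the 18 with a summit in HA-RBN. TRIM24 itself, on chromosome 7 from 138460259 to 138589996 (hg38), had a summit at its lower end in all 6 libraries. That summit held 103 fragments with the control siRNA, 138 with RB1 siRNA, 60 in EV(245-255), 55 in HA-RB(245-255), 10 in EV(RBN) and 28 in HA-RBN. As enrichment over the background of each library these were 249, 256, 320, 220, 27.3 and 44.2.

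DUSP2, a phosphatase of ERK on chromosome 2 from 96143169 to 96145440, had a summit near its upper end in 4 libraries. There were 33 fragments at position 96145510 with RB1 siRNA, 17 at 96145301 in EV(245-255), 16 at 96145467 in HA-RB(245-255) and 18 at 96145479 in HA-RBN. As enrichment over the background of each library these were 61.3, 90.7, 64.0 and 28.4. The EV(RBN) list had its peak at the other end, from 96142812 to 96143149, with 7 fragments. HA-RB(245-255) also had a summit of 4 fragments at 96142248, which is 921 bp from that lower end. With the control siRNA the gene lay inside an interval from 96029399 to 96231453, whose single listed summit, of 39 fragments, lay 63342 bp from the gene. A lower stack of fragments at the gene would not be listed there, so these lists cannot show a summit gained with RB1 siRNA.

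**Figure D1:**
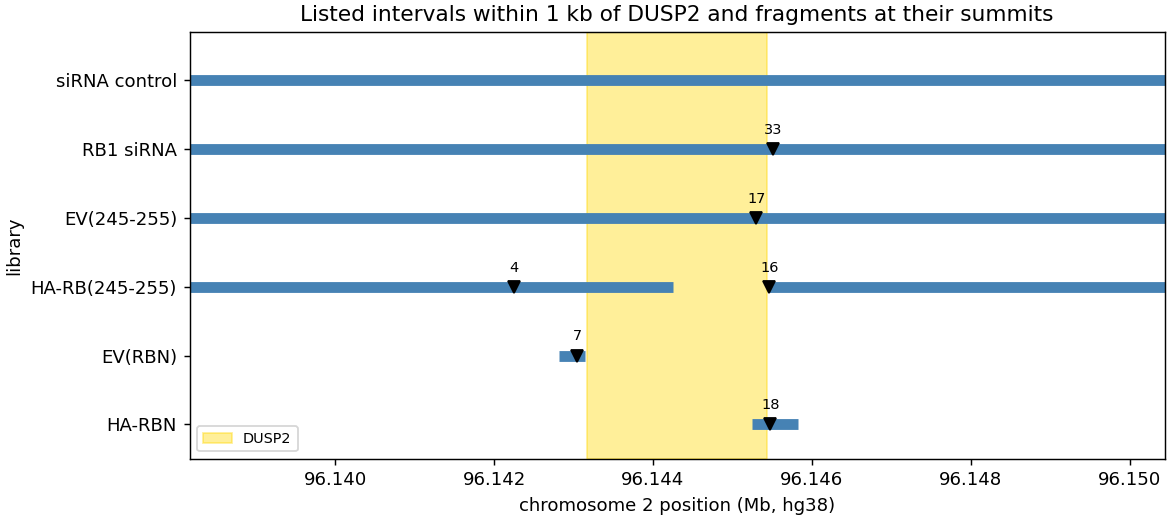
Listed intervals within 1 kb of DUSP2 (blue bars, 1 row per library), with triangles at summits and the number of fragments above each, against the position on chromosome 2 in Mb (hg38); the gene is shaded. Summits near the upper gene end held 33 fragments with RB1 siRNA, 17 in EV(245-255), 16 in HA-RB(245-255) and 18 in HA-RBN, while near the lower end EV(RBN) had 7 and HA-RB(245-255) a second summit with 4. Fragment numbers are not divided by the background, which differs between libraries. The control siRNA row has no triangle because the single listed summit of its interval lies outside the plot.

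The siRNA pair addresses what loss of RB does to the binding of the immunoprecipitated protein. With RB1 siRNA, EZH2, the histone methyltransferase of the polycomb complex, had 219 fragments against 315 with the control siRNA. Its log2 enrichment ratio relative to all shared gene ends was −0.79 (95% interval −1.04 to −0.53). Lower values with intervals below 0 were also found for CBX5, which encodes heterochromatin protein HP1α, at −0.50 (−0.75 to −0.26), the ribonucleotide reductase subunit RRM2B at −0.47 (−0.82 to −0.13), E2F2 at −0.45 (−0.76 to −0.14) and the replicative helicase subunit MCM7 at −0.41 (−0.67 to −0.15). These genes are set apart by intervals that cover counting error only. The SD of the log2 ratio over all shared summits of this pair was 0.436. RB1 itself, on chromosome 13 from 48303751 to 48481890, had 23 fragments at its lower end against 9, at 1.09 (−0.08 to 2.39), which says nothing of how far RB1 was depleted. TRIM24 stood at 0.16 (−0.22 to 0.54).

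Among the 17 DNA replication and E2F targets with a shared gene end, 13 lay below the median of all shared gene ends and 4 above. The list median was −0.19, at percentile 3.13 of random lists, which is inside the ordinary range. RRM2 had −0.30 (−0.67 to 0.07) and MCM4 −0.22 (−0.58 to 0.15). TRIM24 relatives and partners had 6 of 8 below, with a median of −0.22 (percentile 6.94), and in it CBX3 had −0.18 (−0.45 to 0.08) and TRIM28 0.17 (−0.21 to 0.55). The RB pathway had 7 of 13 above, with a median of 0.04 (76.2), CDK4 at 0.15 (−0.19 to 0.49) and E2F8 at −0.07 (−0.38 to 0.24). DUSP genes had 3 of 5 above with a median of 0.10 (76.4), among them DUSP1 at 0.10 (−0.32 to 0.53) and DUSP4 at 0.13 (−0.44 to 0.70). mTOR signalling had 6 of 11 above with a median of 0.05 (58.9), and RHEB, the GTPase that activates the kinase, stood at 0.05 (−0.35 to 0.46). RAS and ERK cascade genes had a median of −0.05 (43.7), with JUN at 0.10 (−0.29 to 0.49). Mitosis genes had −0.09 (15.4), with TTK at −0.43 (−1.08 to 0.21) and PRC1 at 0.42 (−0.18 to 1.02). Medians were 0.10 for p53 targets (85.3), −0.07 for androgen receptor targets (30.3) and 0.08 for ribosomal proteins (72.6). NF-kB, interferon, neuroendocrine and other-organ lists had under 4 shared members. Of the interferon response genes, 4 of 29 had a gene end summit with RB1 siRNA (percentile 1.09) against 8 with the control siRNA (49.0). RB1 siRNA intervals still lay within 1 kb of an end of each of those 8 genes, so none counts as listed only in the control (48.4).

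For 36 genes a gene end summit was listed with RB1 siRNA and no control interval lay within 1 kb of either end. Control siRNA intervals came within 1 kb of an end of 19834 of 20037 genes, and RB1 siRNA intervals of 19874. A missing interval here is a gap in intervals that cover nearly all of the chromosomes, and does not show that binding was missing. The authors' fold enrichment was highest at CCR10, a chemokine receptor gene (3.31, 133 fragments), then NAA80 (2.89, 109 fragments), NOXO1 (2.58) and MED11, a Mediator subunit (2.55). KLF2, a zinc finger transcription factor, had 1.81, and the peak shared by PSMB1 and TBP, the TATA-binding protein, had 1.76. DCXR followed with 1.76, TMEM150A with 1.74, TOMM6 with 1.72 and RPS24, the ribosomal protein of this set, with 1.72. For 22 genes the converse held. They were led by ZNF250 (2.46, 89 fragments), the neural transcription factor POU3F2 (1.98, 60 fragments), FKBPL (1.59) and IMP3 (1.54), with LMNTD2, ANXA4, GMPPB, TP53RK, SOX4 and GRB7 from 1.52 down to 1.29. POU3F2 was 1 of 4 neuroendocrine genes with a control summit (percentile 99.2, but an ordinary 49.2 with a 2 kb window and 89.8 with lists of the same length).

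Of the control siRNA peaks 98.5% (98.3 to 98.7) overlapped an RB1 siRNA peak, and 98.5% did so when placed at random. New peaks made up 1.36% (1.24 to 1.49) of the RB1 siRNA list. The intervals covered 95.4% and 93.5% of the chromosomes, so overlap could not separate these libraries. At 4783 shared summits the median log2 ratio was −0.12 (−0.13 to −0.10), and 155 of them (3.24%) lay more than 1 log2 unit from it. Of the 36 and 22 genes above none remained when the scored peak needed −log10 q of at least 5. Which direction was larger depended on the setting, with 28 and 282 for lists of the same length, 6 and 44 with both lists at that q value and 24 and 8 with both at fold enrichment of at least 5. With absence judged by summits in place of intervals, and no such limit, 2729 genes were listed only with RB1 siRNA and 1637 only with the control siRNA.

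**Figure D2:**
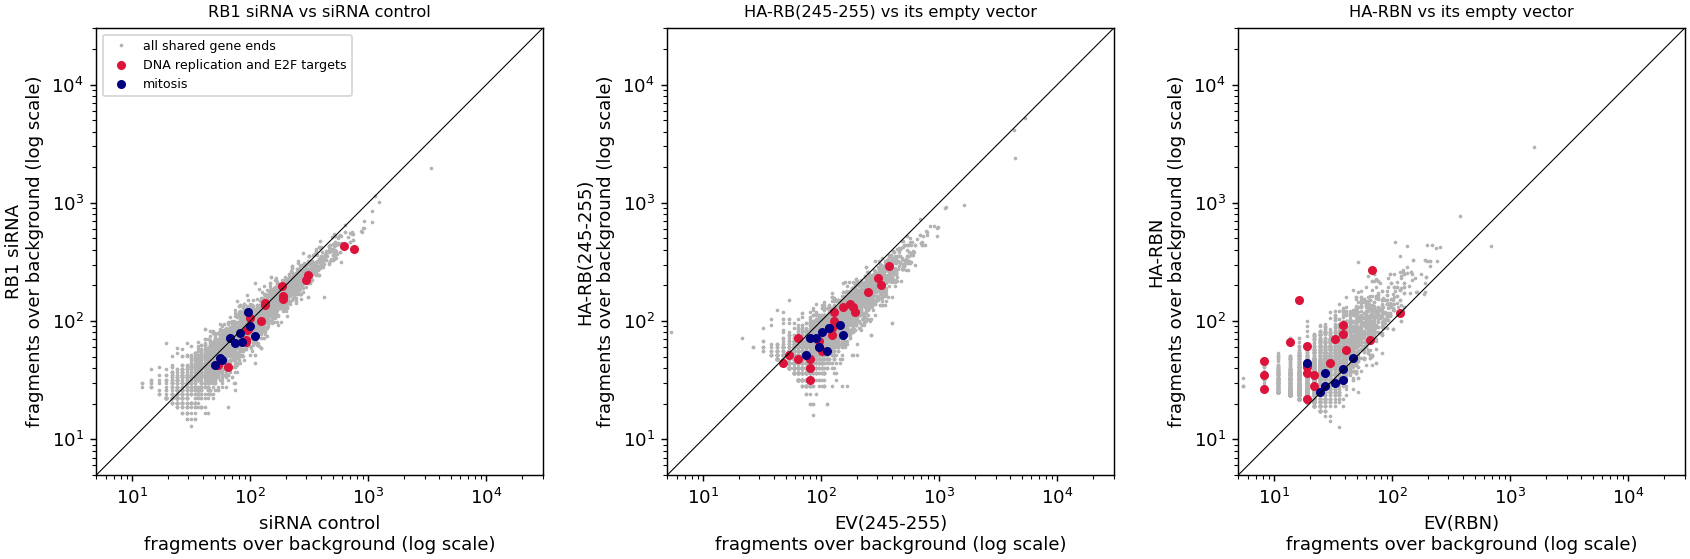
Fragments over background at each gene end with a shared summit, condition on the vertical axis and control on the horizontal axis, both on log scales without units, in a panel for each comparison; grey points are all shared gene ends, red the DNA replication and E2F targets, blue the mitosis genes, and the line marks equality. The median log2 ratio of the grey points is −0.12 for RB1 siRNA, −0.47 for HA-RB(245-255) and 0.68 for HA-RBN, where 13 of 20 red points and 1 of 8 blue points lie above it.

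The 245-255 pair addresses what an HA-tagged RB fragment around S249 and T252 does to binding. GADD45A, a p53 target that acts in growth arrest, had 26 fragments with HA-RB(245-255) against 47 with its empty vector, a relative log2 ratio of −0.80 (−1.55 to −0.08). Among the list members that the rule names in this pair, its interval alone excluded the median of all shared gene ends. Across so many members, some such intervals arise by chance. DUSP16 had 25 against 43, at −0.73 (−1.50 to 0.02). TRIM24 had −0.07 (−0.63 to 0.48) and DUSP2 −0.03 (−1.11 to 1.04). MTOR, on chromosome 1 from 11106535 to 11262551, had a summit of 14 fragments at its upper end with HA-RB(245-255) and 1 of 5 fragments at its lower end with the empty vector. RB1 had 6 fragments at its lower end against 9.

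p53 targets had 7 of 10 shared gene ends below the median of all, with a list median of −0.23 (percentile 4.54), TP53I3 at −0.36 (−0.83 to 0.11), RRM2B at −0.01 (−0.50 to 0.49) and FDXR at 0.37 (−0.15 to 0.90). DNA replication and E2F targets had 10 above and 12 below, with a median of −0.02 (42.6), PCNA, the sliding clamp of replication, at 0.09 (−0.40 to 0.59) and MCM7 at 0.08 (−0.47 to 0.63). TRIM24 relatives and partners had 7 of 8 below, with a median of −0.13 (19.4), CBX3 at −0.35 (−0.89 to 0.17) and CBX5 at −0.33 (−0.80 to 0.14). mTOR signalling had 11 above and 12 below, with a median of −0.05 (31.5), EIF4B, a translation factor downstream of the pathway, at −0.42 (−0.95 to 0.09) and AKT1S1 at 0.03 (−0.47 to 0.54). DUSP genes had 5 above and 4 below, with a median of 0.05 (69.9), DUSP1 at 0.33 (−0.28 to 0.96) and DUSP4 at −0.51 (−1.38 to 0.34). Androgen receptor targets had a median of 0.10 (80.2), with C1orf116 at −0.08 (−0.61 to 0.44). The RB pathway had 0.01 (54.8), with CDK4 at −0.03 (−0.42 to 0.35). The RAS and ERK cascade had −0.03 (44.0), with SHC1 at 0.23 (−0.26 to 0.72). Ribosomal proteins had 0.05 (65.9). NF-kB response genes had 0.05 (59.3) and mitosis genes 0.00 (47.9). Interferon, neuroendocrine and other-organ lists had under 4 shared members.

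Only with HA-RB(245-255) were 33 genes listed at a gene end. Empty vector intervals came within 1 kb of an end of 19946 of 20037 genes, and HA-RB(245-255) intervals of 19931. A missing interval is again a gap in the wide intervals and does not show that binding was missing. The peak shared by FBXL6 and CATSPERQ had the highest fold enrichment (2.64, 33 fragments), followed by PAXX, a DNA end-joining factor (2.58, 33 fragments), ADAM15 (2.29), TRMT112 (2.24), UFSP1 (2.15), METTL26 (2.1), NAXE (2.1), TUBB4B (2.08) and the mucin gene MUC1 (2.02). LAMTOR2, a lysosomal anchor of mTORC1, had 1.85 with 17 fragments, and the interferon-induced BST2 had 1.23. Only with the empty vector were 43, led by NDUFA2 of respiratory complex I (2.84, 43 fragments), the immediate-early gene IER5 (2.41), HERPUD1 of the endoplasmic reticulum stress response (2.28), FANCF of the Fanconi pathway (1.85), ZNF281 (1.81) and the ribosomal gene RPLP2 (1.81). LAG3, HIGD2A, MYOM1 and MIA had 1.72, 1.71, 1.62 and 1.59. The prostate homeobox gene HOXB13 was listed at 1.15 with 4 fragments.

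Of the empty vector peaks 98.98% (98.9 to 99.1) overlapped an HA-RB(245-255) peak, and 98.9% did so at random. New peaks made up 0.663% (0.612 to 0.717), and the intervals covered 95.7% and 92.9% of the chromosomes. At 6244 shared summits the median log2 ratio was −0.46 (−0.48 to −0.42), and 261 (4.18%) lay more than 1 log2 unit from it. The E2F list median turned to 0.041 when at least 40 fragments were asked for. Of the 33 and 43 genes above none remained at −log10 q of at least 5 in the scored list. Here too the larger direction depended on the setting, with 47 and 18 for both lists at that q value, 39 and 17 for both at fold enrichment of at least 5, and 32 and 83 for lists of the same length. Judged by summits, without that limit, 2837 genes were listed only with HA-RB(245-255) and 2820 only with its empty vector.

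The RBN pair addresses what expression of the RBN insert does to binding. DNA replication genes stood above other shared gene ends with HA-RBN. Their list median was 0.43 over 20 genes, at percentile 99.9 of random lists, with 13 above and 7 below the median of all. EZH2 had 96 fragments against 6 with the empty vector, a relative log2 ratio of 2.53 (1.35 to 4.01), and MCM7 had 173 against 25, at 1.32 (0.71 to 1.98). The enrichment of EZH2 was 151 in HA-RBN and 16.4 in EV(RBN). It was 763 with the control siRNA, 407 with RB1 siRNA, 251 in EV(245-255) and 176 in HA-RB(245-255). The EZH2 ratio therefore rests on a low value in the single EV(RBN) library. Mitosis genes with a shared gene end stood below, with a list median of −0.63 over 8 genes (percentile 0.32) and 7 of 8 below. Those 8 are a part of the list, as 22 of 25 members had a gene end summit in both libraries. A further 3 were listed only with HA-RBN and 0 only with EV(RBN). Over all mitosis gene ends with a summit the median was 5.5 fragments against 5 in EV(RBN) (percentile 66.1). In HA-RBN it was 15 against 10 (94.4), so both were ordinary and the low median holds for the shared members only. In EV(RBN) alone the DNA replication list was ordinary in strength though not in its share of gene ends with a summit, with a median of 5 fragments against 5 at all gene ends (percentile 45.4), while in HA-RBN it had 19 against 10 (100).

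Further DNA replication genes, picked after their values were seen, were PRIM1, the primase subunit, at 1.80 (0.11 to 4.16), MCM3 at 1.60 (0.26 to 3.29), POLD3 at 1.40 (−0.33 to 3.78), MCM5 at 1.00 (−0.17 to 2.41) and MCM4 at 0.60 (−0.26 to 1.56). PCNA had 0.43 (−0.51 to 1.49) and the maintenance methyltransferase DNMT1 0.33 (−0.55 to 1.31). Not every member lay above, since the helicase cofactor CDC45 had −0.69 (−1.25 to −0.11) and ORC6 −0.60 (−1.35 to 0.18). EZH2 and MCM7 were picked in the same way for this pair. Among mitosis genes chosen so, the kinase AURKA had −0.96 (−2.02 to 0.14), NUF2 −0.81 (−1.93 to 0.36), the motor KIF11 −0.64 (−1.91 to 0.72) and UBE2C −0.63 (−1.82 to 0.65). MAD2L1 of the spindle checkpoint was the member above, at 0.53 (−0.70 to 1.97). Each mitosis member named here has an interval that includes 0. Between control libraries the E2F list median was −1.01 in EV(RBN) over the control siRNA (percentile 0), −0.53 in EV(245-255) over the control siRNA (0.16) and −0.13 in EV(RBN) over EV(245-255) (43.0). The mitosis list had 0.43 in EV(RBN) over the control siRNA (96.2), 0.10 in EV(245-255) over the control siRNA (63.5) and 0.41 in EV(RBN) over EV(245-255) (99.5), of which the first 2 are ordinary.

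TRIM24 had 28 fragments against 10, at 0.01 (−1.07 to 1.22), so it stood with the shared gene ends as a whole. TRIM24 relatives and partners had 7 of 10 above, with a median of 0.11 (76.9), CBX3 at 0.39 (−0.09 to 0.90), TRIM28 at 0.27 (−0.42 to 1.01) and CBX5 at −0.39 (−0.81 to 0.03). DUSP genes had 5 of 6 above with a median of 0.30 (92.5), and DUSP12 stood at 0.33 (−0.84 to 1.68). DUSP26 was listed only with HA-RBN (fold enrichment 4.05, 7 fragments). mTOR signalling had 10 above and 10 below, with a median of −0.04 (41.8). Its members RRAGD, a Rag GTPase that recruits mTORC1 to lysosomes (6.17, 10 fragments), PIK3R1 (4.11), IRS1 (3.86) and FNIP2 (3.06) had peaks only with HA-RBN. They were 4 of the 6 members without an EV(RBN) interval at a gene end, an ordinary share (percentile 77.5) against 49.9% of all such genes. With both lists at −log10 q of at least 5 the share of mTOR signalling genes gained lay above the ordinary range. MTOR had a peak at its upper end in both, with 11 fragments in HA-RBN and 5 in EV(RBN). RB pathway genes had a median of 0.09 (62.8). RB1 had a peak at its lower end, from 48303752 to 48304557, only with HA-RBN (4.11, 6 fragments). CDKN1C (4.10) and E2F5 (3.06) also had gene end peaks only there, which made 3 of 4 eligible members (an ordinary 81.2). This share too lay above the ordinary range with both lists at −log10 q of at least 5. HA-RBN also listed a peak inside RB1 from 48426842 to 48427533 (5.87, 9 fragments). The p53 targets had 0.07 (55.9), with PLK3 at 0.70 (−0.05 to 1.52) and TP53I3 at −0.43 (−1.04 to 0.19). Ribosomal proteins had −0.11 (19.3), androgen receptor targets 0.08 (74.7), the RAS and ERK cascade −0.05 (47.0), NF-kB genes −0.09 (52.7) and interferon genes −0.29 (22.3). Neuroendocrine and other-organ lists had under 4 shared members.

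**Figure D3:**
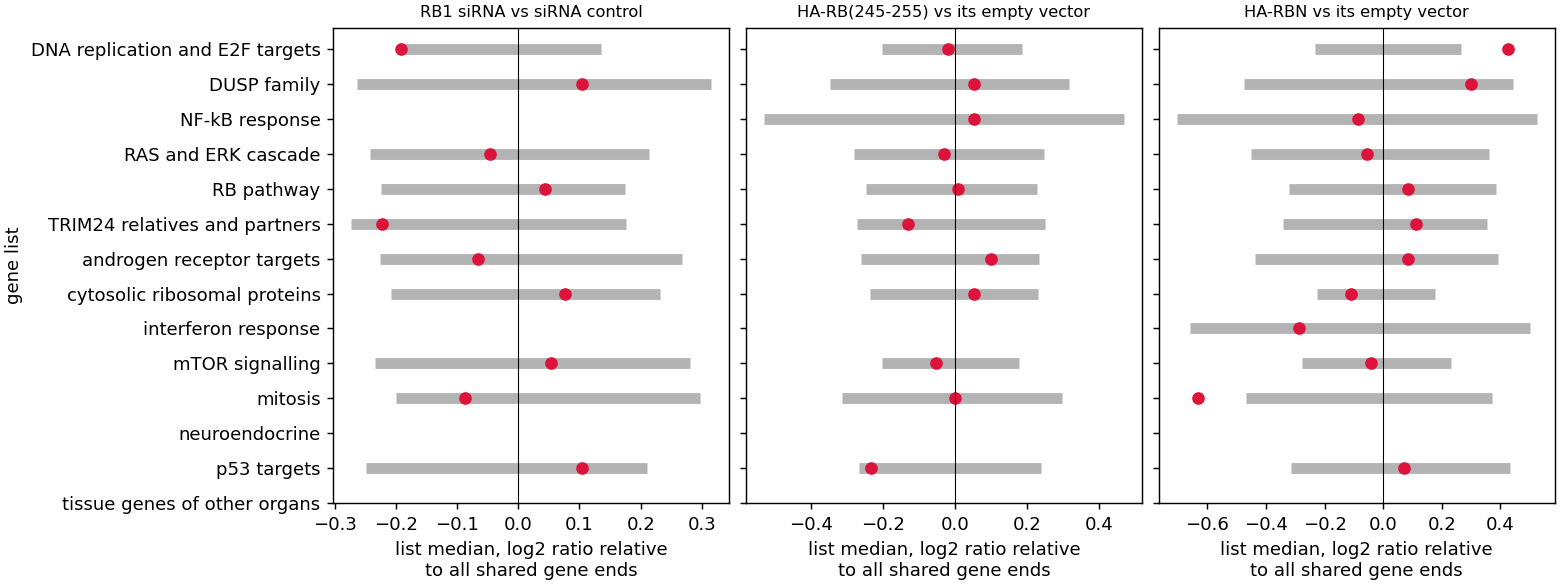
Median log2 ratio of each gene list relative to all shared gene ends (red points, no units) in a panel for each comparison; grey bars span the middle 95% of random lists of the same size, and lists with under 4 shared genes have no point. Random lists were matched by decile on the summed log2 enrichment of both libraries. In the HA-RBN panel the DNA replication and E2F list at 0.43 and the mitosis list at −0.63 lie outside their bars.

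Gene end peaks of 3488 genes were listed only with HA-RBN. The highest fold enrichments were at ELK4, an ETS transcription factor that works with SRF (9.57, 24 fragments, −log10 q 17.1, chromosome 1 from 205631968 to 205632608), RXYLT1 (9.44), GIT2 (9.42, 31 fragments, −log10 q 20.6), FAM200C (8.97), DTX4 of the Notch pathway (8.76), the kinase gene SNRK (8.74) and the small GTPase RAP1B (8.58). BIRC3, an apoptosis inhibitor and NF-kB target, had 8.37 with 17 fragments on chromosome 11 from 102317119 to 102317919, NDFIP1 8.25, and the peak between KIAA0825 and SLF1 8.19. All 5 RAS and ERK cascade genes without a control peak had one with HA-RBN (percentile 98.4), among them IER3 (6.14), NRAS (4.28), RPS6KA3 (4.22) and FOSL1 (3.78). So did 6 of 7 androgen receptor targets (an ordinary 96.6, with 92.9 for a 2 kb window, 89.5 with both lists at −log10 q of at least 5 and 99.01 with lists of the same length), among them HERC3 (5.39), STEAP4 (3.67) and TMPRSS2 (3.19), against 49.9% of all such genes. The replication genes POLA2 (5.60), GINS1 (3.14) and CCNE1 (2.45), the mitosis genes CENPE (5.82), BUB1 (4.28) and BIRC5 (3.43), and the interferon response genes RSAD2 (4.94), PSMB8 (4.28) and MX1 (3.74) were also listed only with HA-RBN. Eligible members in this set were 3 of 4 replication genes, 3 of 3 mitosis genes and 7 of 10 interferon genes. Percentiles were an ordinary 81.2 for replication and 88.9 for interferon, and mitosis had too few members for a percentile. With both lists at −log10 q of at least 5 replication genes lay at 100. NCAM1 (3.96) and CHGB (3.67) were 2 of the 4 neuroendocrine genes in this set, from 6 eligible (an ordinary 77.5). Of other-organ genes 7 of 24 were in it (percentile 2.22, with an ordinary 7.94 for a 2 kb window and 6.85 with lists of the same length, and 0 with both lists at −log10 q of at least 5).

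Only with EV(RBN) were 919 genes listed at a gene end. PIAS4, a SUMO ligase, led with 5.77 (12 fragments, −log10 q 5.39, chromosome 19 from 4007120 to 4007570), before NPIPB15 (4.92), CYTH1 (4.81), DAP (4.77), MPO (4.71), C1QTNF4 (4.68), CFAP97D1 (4.59), the peak of SLC24A1 and INTS14 (4.59), MRPS10 (4.59) and MS4A5 (4.39). Of genes with a control peak, 7.62% were in this set. None of 58 ribosomal protein genes were (percentile 0.445, with 2.27 for a 2 kb window, 0.1 with lists of the same length and an ordinary 87.3 with both lists at −log10 q of at least 5), and none of 43 mTOR signalling genes (1.60, with an ordinary 3.56 for a 2 kb window and 0.26 with lists of the same length). ORC1 was the member from 43 replication genes (2.59, 4 fragments), and BST2 (3.79) was 1 of 3 among 18 interferon genes.

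Of the EV(RBN) peaks 32.6% (32.4 to 32.8) overlapped an HA-RBN peak, against 10.2% at random, and 79.4% (79.2 to 79.5) of HA-RBN peaks were new. With the HA-RBN list alone held to −log10 q of at least 5, 7.80% were new, so most new peaks were weak ones, and 73.4% were new with both lists held to it. At 6928 shared summits the median log2 ratio was 0.57 (0.55 to 0.59), and 865 (12.5%) lay more than 1 log2 unit from it. With both lists held to −log10 q of at least 5, 91.4% of EV(RBN) peaks were kept. Of the genes listed only in 1 library, 209 for HA-RBN and 1 for EV(RBN) remained when the scored peak needed that q value.

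The control libraries show how far libraries of different experiments differ without an RB construct or RB1 siRNA. EV(RBN) has no IgG partner, and its list covered 2.75% of the chromosomes, against 95.4% for the control siRNA and 95.7% for EV(245-255). Overlap, new and shared-base shares with EV(RBN) therefore cannot tell the experiment from the form of the lists. Of the control siRNA peaks 99.8% overlapped EV(245-255) and 87.9% overlapped EV(RBN), against 99.9% and 79.0% at random. Of EV(245-255) peaks 66.0% overlapped EV(RBN), against 57.1% at random. New peaks made up 0.921%, 4.75% and 5.77% in these comparisons, and shared bases as a share of all covered bases were 91.6%, 2.71% and 2.61%. The SD of the log2 ratio at shared summits was 0.802, 0.835 and 0.982, against 0.436 for RB1 siRNA, 0.486 for HA-RB(245-255) and 0.656 for HA-RBN. More than 1 log2 unit from the median lay 18.4%, 21.1% and 29.0% of those summits.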

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

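The tests of libraries of different experiments, of the empty vector library and of the scaling of libraries were chosen only after the results were seen, and the limit for the empty vector library was widened to all its control comparisons once a first outcome was known.

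HA-RBN listed 3.61% (95% interval 3.54 to 3.68) of its peaks on sequences outside chromosomes 1-22, X and Y, which the comparisons do not use, against 2.63% (2.55 to 2.70) in EV(RBN). The other libraries had from 3.48% to 3.91%. The median log2 enrichment ratio at shared summits was −0.46 with HA-RB(245-255) and 0.57 with HA-RBN, each over its own empty vector, so the plasmid pairs went opposite ways. That difference was not tested, since each ratio rests on 1 library per group.

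HA-RBN listed more strong summits than EV(RBN), 32426 against 13677 with −log10 p of at least 5 over the background. Its background was 1.73 times that of EV(RBN), so its fragments were thinned to the same background. The thinned list still held 19069.8 strong summits on average, 1.39 times the empty vector number (1.38 to 1.40 over 20 draws), where depth as the whole cause allowed at most 1.1 times. A better yield of the immunoprecipitation and an effect of the RBN insert both stay open and untested, because either goes with the single HA-RBN library.

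DNA replication and E2F targets stood above other shared gene ends in HA-RBN over EV(RBN). Among gene ends matched on the number of control siRNA fragments, 14 of these genes had a median of 0.42 at percentile 98.3, just past the 0.39 that bounds random lists, which argues against strong sites alone as the cause. Control libraries differed at the same list without any RB insert, by −1.01 for EV(RBN) over the control siRNA (percentile 0), −0.53 for EV(245-255) over it (0.16) and −0.13 for EV(RBN) over EV(245-255) (43.0). Within EV(RBN) the strength of the list lay at percentile 45.4 while it lay at 98.6 or higher in each of the other 5 libraries, yet 43 of 50 members had a summit there and the ratio to EV(245-255) was ordinary, so whether EV(RBN) stands apart cannot be told. An effect of the RBN insert stays open and would need a repeat of the empty vector.

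The 4 lists with an IgG partner covered from 92.9% to 95.7% of the chromosomes, while EV(RBN) covered 2.75% and HA-RBN 4.89%. If the immunoprecipitated library had been scaled down to a much smaller control library, summit heights would come in whole multiples of 1 small step. At least 99.3% of summits did in each of the 4 lists, where a multiple within 0.1 of whole counted. The steps correspond to scaling by 60.3, 56.8, 23.1 and 19.5 times. This is consistent with scaling as the source of the wide intervals. No biological explanation was tested.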

How the results depend on the processing

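Absence judged by summits, and every setting for fragments at shared summits, were chosen only after the results were seen. The settings below give values for RB1 siRNA, HA-RB(245-255) and HA-RBN, in that order. Control peaks kept were 32.4%, 28.3% and 15.8% with a 50% reciprocal overlap, and 29.9%, 18.5% and 18.4% with summits within 250 bp. They were 49.2%, 72.1% and 91.4% with both lists at −log10 q of at least 5, 76.4%, 76.9% and 79.1% with both at fold enrichment of at least 5, and 90.4%, 97.6% and 27.0% with lists of the same length. They were 100%, 100% and 98.5% with the control list alone at −log10 q of at least 5, and 98.1%, 98.7% and 33.0% on all sequences. New condition peaks were 80.1%, 77.2% and 89.8% with reciprocal overlap, 81.7%, 85.1% and 88.1% with summits, 19.2%, 43.9% and 73.4% at that q value in both lists, 37.8%, 38.1% and 65.0% at that fold, and 0.264%, 0.348% and 73.7% at the same length. They were 0%, 0.935% and 7.80% with the condition list alone at that q value, and 2.09% and 0.923% on all sequences, where HA-RBN stayed within its interval. The settings with a q value or fold limit score fewer peaks. Under reciprocal overlap and summits the share kept also fell in the RBN pair, whose widest peaks were 5862 bp in EV(RBN) and 4514 bp in HA-RBN. The cause of these shifts was not tested.

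Genes listed only in the condition numbered 6 for RB1 siRNA with both lists at −log10 q of at least 5. With the scored list alone at that value there were 0, 0 and 209, and with absence judged by summits 2729 and 2837 for the siRNA and 245-255 pairs. Genes listed only in the control numbered 44, 18 and 36 with both lists at that q value, 8, 17 and 156 at fold enrichment of at least 5, and 282 and 83 at the same length for the siRNA and 245-255 pairs. With the scored list alone at that q value there were 0, 0 and 1, and judged by summits 1637, 2820 and 1443. At the settings where only the control count moved, the condition counts were 28 for RB1 siRNA at the same length and 24 at that fold, and 47, 39 and 32 for HA-RB(245-255) with both lists at that q value, at that fold and at the same length, so for both pairs the larger direction depended on the setting. In all, 15 counts of condition-only and 7 of control-only genes stayed within 1.5 times. The cause was not tested.

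The E2F list median kept its sign in 8 of 9 settings and turned to 0.041 for HA-RB(245-255) with at least 40 fragments. The mitosis list median kept its sign in 5 of 8, and for HA-RB(245-255), where it was 0.00, it turned to −0.053 with at least 10 fragments, −0.055 with at least 40 and −0.0062 with a 2 kb window. With at least 40 fragments HA-RBN had too few mitosis members for a median. The median log2 ratio at shared summits stayed within its interval in 6 of 9, and for HA-RBN it was 0.38 with at least 10 fragments, 0.69 with at least 40 and 0.55 with summits within 100 bp. The percentile of a gene list stayed on the same side of the limits of the ordinary range in 99 settings and crossed a limit, inwards or outwards, in 14. The percentiles after crossing were 49.2 with a 2 kb window and 89.8 at the same length for control-only neuroendocrine genes of the siRNA pair, and the other 12 belong to HA-RBN. Among genes gained they were 100 for E2F targets, 99.98 for the RB pathway and 99.995 for mTOR signalling with both lists at −log10 q of at least 5, 99.01 for androgen receptor targets at the same length, and for other-organ genes 7.94 with a 2 kb window and 6.85 at the same length. Among genes lost they were 87.3 for ribosomal proteins at that q value, 3.56 for mTOR signalling with a 2 kb window, 2.36 for E2F targets and 99.9 for interferon genes at the same length, and for other-organ genes 98.2 with a 2 kb window and 98.6 at the same length. Overlaps between control libraries stayed in 1 of 21, and peak locations in 0 of 18. The cause was not tested.

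Many listed summits rest on few fragments. Those with up to 3 fragments made up 27.5% of the control siRNA list, 29.7% for RB1 siRNA, 62.7% in EV(245-255), 65.9% in HA-RB(245-255), 72.5% in EV(RBN) and 55.4% in HA-RBN. A fold enrichment of 5 needed 244, 231, 94, 80, 6 and 8 fragments in the same order. No paired analysis was possible because each group has 1 library. Both motif alternatives were not run, since motif searches need a genome sequence.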

Other observations

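The strength of lists within each library was computed only after the data were seen, and no test was made of it in this part.

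Strength within each library also set gene groups apart. RB pathway genes, among them E2F2, CDK4 and CDKN2C, had a median of 52 fragments at their gene ends in the control siRNA library against 25 over all gene ends with a summit (percentile 99.6), and 58.5 against 28 with RB1 siRNA (99.8). They had 24 against 12 in EV(245-255) (99.7), 21 against 11 in HA-RB(245-255) (99.2), 7 against 5 in EV(RBN) (94.7) and 20 against 10 in HA-RBN (99.7). TRIM24 relatives and partners, among them the heterochromatin genes CBX3 and CBX5 and the co-repressor TRIM28, lay at percentiles 99.8, 94.6, 98.96, 84.3, 96.1 and 99.9 in the same order. Cytosolic ribosomal proteins lay at 76.5, 65.9, 84.2 and 93.5 in the first 4 libraries and at 99.9 and 100 in EV(RBN) and HA-RBN. Interferon response genes had a median of 4 fragments in HA-RB(245-255) (percentile 0.2) and 5 in its empty vector library (2.71), and lay at 27.6, 27.3, 46.2 and 17 in the control siRNA, RB1 siRNA, EV(RBN) and HA-RBN libraries. Genes of other organs had a median of 10 fragments with RB1 siRNA (an ordinary 3.16), and 4, 4, 3 and 4.5 in EV(245-255), HA-RB(245-255), EV(RBN) and HA-RBN, with no percentile above 0.96 in these 4. The control siRNA library had 1 such gene and gives no value.

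DNA replication and E2F targets had a median of 41 fragments at their 31 summits in the control siRNA library against 25 over all gene ends with a summit (percentile 98.9). With RB1 siRNA the median was 57 against 28 (100), in EV(245-255) 18 against 12 (98.6), in HA-RB(245-255) 18 against 11 (99.2), in EV(RBN) 5 against 5 (45.4) and in HA-RBN 19 against 10 (100).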
